A study of Mus musculus with 6 samples.

How the data were processed

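Placenta of mice at embryonic day 12.5 was compared between wild type and Slc6a4-/-, with 3 libraries of each genotype. Per the labels, total RNA was extracted with a Qiagen AllPrep kit and libraries were made with an Illumina TruSeq RNA kit, which does not mark strand. Groups and replicate numbers were taken from the labels.

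The deposited values are raw counts per gene, which the authors made with featureCounts from reads aligned to GRCm38 with HISAT2 2.0.5, per the submitters' processing notes. Those notes name Subread 2.0.1, while the file header gives featureCounts 2.0.0. Per the file header, reads were counted in pairs over exons of the Ensembl release 99 annotation, with no option for strand, for reads that map to several places or for reads that overlap several genes. Such reads were therefore left out, which lowers the counts of near-identical members of the prolactin, Ceacam, Psg, cathepsin and Serpina1 families and makes their levels uncertain. Reads of overlapping genes on opposite strands cannot be told apart. The total count was between 94234683 and 121168826 per library, and 99.95% or more of it fell in the genes tested. At this depth counting error is small for genes above 1 CPM (counts scaled to the library total by edgeR), and the spread between libraries limits the precision.

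Symbols were taken from GENCODE release M21, which matched 55144 of the 55471 gene identifiers and left 327 by identifier only. Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr and scaled with TMM factors, and the genotypes were compared with edgeR 4.0.16 by the quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are given as CPM and use the TMM factors. Lists of genes were fixed before the data were examined, 33 in all, for placental cell types, other cell types that a dissected placenta could hold, transport and metabolism, stress, serotonin handling and the Y chromosome. Of their members 3 matched no gene, Hbb-b1, Hbb-b2 and Ahsp. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and each member was also adjusted over its list alone. The score of a list in a library is the mean over members of log2 CPM, with a prior count of 0.5, minus the gene's mean over the 6 libraries.

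The genes named were set by a rule fixed before the data were examined. It takes Slc6a4, up to 12 genes per direction that pass with a mean log2 CPM of at least 1, no overlap of the groups and a symbol that is not a predicted model, or up to 6 per direction with the lowest p under the same limits where fewer than 5 pass, up to 4 members of each list with the lowest p, and the Y-linked genes and Xist. Members of lists outside the placenta that were not called are given by list only. Exceptions are the Y-linked genes, Erv3 of the decidual stroma list and Mmp9 of the neutrophil list, which is also in the matrix remodelling list. Yolk sac genes beyond the 4 of the rule, and Gm12343 and S100g, were chosen after their values were seen.

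Alternatives were RLE and upper-quartile factors, no factors, no filter, a filter at 1 CPM in 3 libraries, each library left out, the replicate number as a block, a term for the form of the sample names, counts thinned to the smallest library, DESeq2 1.42.0, limma-voom, robust dispersion, the 50 genes with most counts left out, other thresholds, camera with an estimated correlation and fry. A test of regions around Slc6a4 had been planned for the case that at least 10 genes were called and was not run, because edgeR called 0 at an adjusted p under 0.05, with 387 at an unadjusted p under 0.05 and 64 called by DESeq2. A test of the genes around Slc6a4 whose groups do not overlap was run in its place, after the data were seen. All pairs of the 6 libraries were compared by a chi-square test of their counts, and the lowest value per degree of freedom was 43.5, between WT replicate 1 and Slc6a4-/- replicate 2, so no library was a repeat of another. The scripts were tested on simulated counts with 200 changed genes.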

Results

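The series measured gene expression by RNA sequencing in mouse placenta at embryonic day 12.5 in 2 genotypes, wild type (WT) and Slc6a4-/-. Slc6a4 encodes the serotonin transporter, which takes serotonin up from outside the cell. Each genotype had 3 libraries, 6 in all. The deposited table held 55471 genes, and the total count per library was 96393687, 97512835 and 99043038 for WT replicates 1, 2 and 3 and 121168826, 107358078 and 94234683 for Slc6a4-/- replicates 1, 2 and 3. The labels do not say that the replicates are separate placentas or animals, so the p-values measure only the spread between these samples, which may be technical.

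The targeted gene was read first, because it checks the labels. Slc6a4 (ENSMUSG00000020838, chromosome 11, 76998603 to 77032340, plus strand, GRCm38) was higher in the libraries labelled Slc6a4-/-, against the direction of the label. Its level was 8.38, 6.75 and 5.85 CPM (counts scaled to the library total) in the libraries labelled WT, a mean of 6.99 ± 1.28 (SD, n = 3). In the libraries labelled Slc6a4-/- it was 12.5, 14.3 and 10.2 CPM, a mean of 12.3 ± 2.04 (SD, n = 3). These levels rest on raw counts of 822, 635 and 581 against 1427, 1606 and 983. The log2 fold change was 0.82 ± 0.21 (SE), every library of the 1 group lay above every library of the other, and edgeR gave an unadjusted p of 0.00614 that did not pass after adjustment over all genes (adjusted p = 1.00). The exact two-sided permutation p of the CPM values was 0.1, the smallest that 3 against 3 libraries allow. The deposited count sums all exons of the gene and the part deleted is not given in the sources used here, so reads from exons outside that part count towards the level. Every direction below is therefore one between libraries as labelled.

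Gm12343, a minus-strand gene inside Slc6a4, was near absent from the libraries labelled WT. It lies on chromosome 11 from 77008914 to 77009873 and its exons fall in introns of Slc6a4. It had 1, 0 and 1 counts in the libraries labelled WT and 15, 17 and 18 in those labelled Slc6a4-/-. From library totals without TMM factors this gave a CPM ratio of 22.7, with an exact 95% interval from 5.96 to 193 that covers counting error only. A count of 0 in WT replicate 2 allows up to 3.69 at the same confidence. Its unadjusted p in edgeR, 2.46e-04, did not pass after adjustment (adjusted p = 1.00), while DESeq2 gave Gm12343 an adjusted p of 0.0366. The counting did not use strand, so reads of Gm12343 cannot be told from reads of unspliced Slc6a4 RNA. The gene was chosen after its values were seen.

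**Figure D1:**
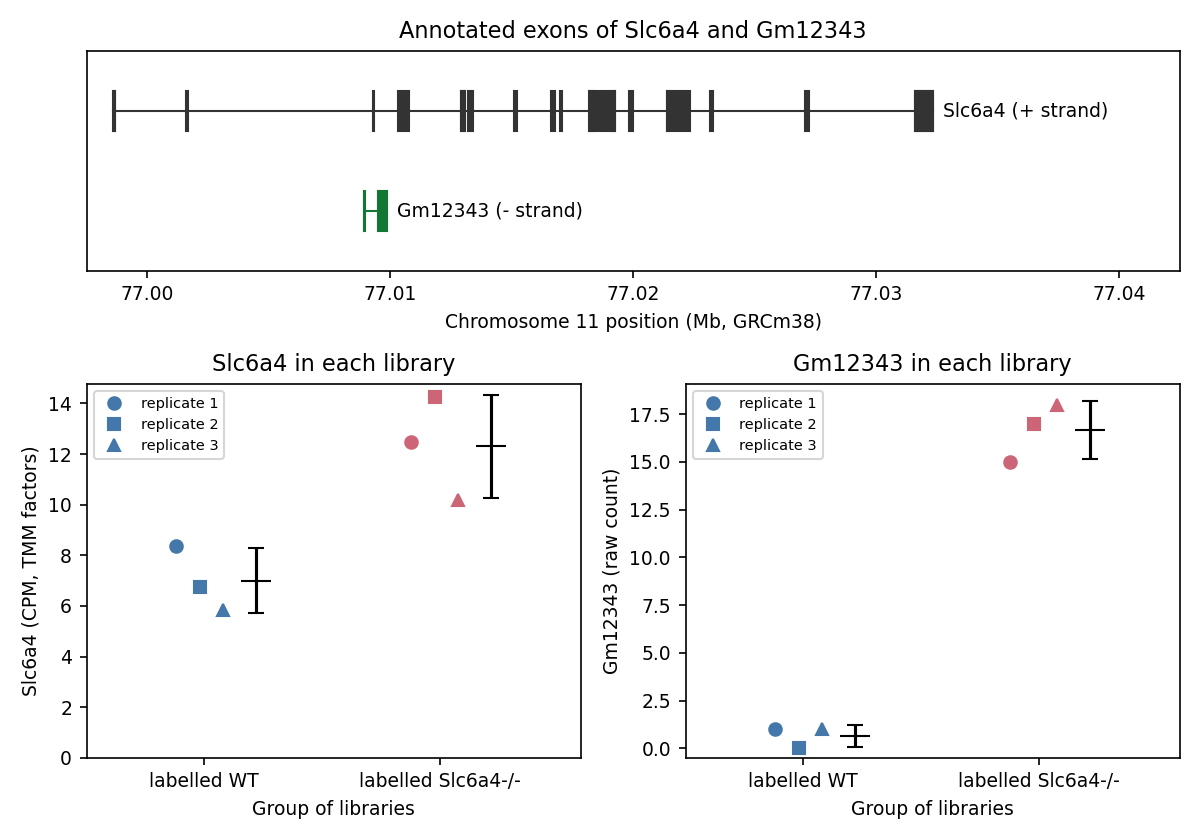
Top, annotated exons of Slc6a4 and Gm12343 along chromosome 11 in Mb. Bottom, Slc6a4 in CPM and Gm12343 in raw counts, with 1 point per library and the mean and SD of each group of 3; Slc6a4 lies between 5.85 and 8.38 CPM in the libraries labelled WT and between 10.2 and 14.3 in those labelled Slc6a4-/-.

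The comparison of the genotypes asks which placental genes differ when the serotonin transporter gene is targeted. Among single genes with a mean log2 CPM of at least 1, groups that do not overlap and a symbol that is not a predicted model, those with the lowest p higher in the libraries labelled Slc6a4-/- were Kng2, which encodes a kininogen, at 3.69 ± 0.64 against 1.36 ± 0.25 CPM (SD, n = 3 each), the collagen genes Col9a3 (4.04 ± 1.65 against 1.07 ± 0.16) and Col2a1 (4.13 ± 2.65 against 0.34 ± 0.31), Fmo1, a flavin-containing monooxygenase (26.9 ± 6.39 against 13.2 ± 1.43), the microvillus protein gene Vil1 (4.30 ± 2.60 against 0.64 ± 0.26) and Irf6 (5.38 ± 1.80 against 1.82 ± 0.59). The log2 fold changes were 1.44 ± 0.24 (SE) for Kng2, 1.92 ± 0.35 for Col9a3, 3.59 ± 0.79 for Col2a1, 1.03 ± 0.20 for Fmo1, 2.74 ± 0.60 for Vil1 and 1.56 ± 0.34 for Irf6. Under the same limits, those with the lowest p in the other direction were Naa11 (log2 fold change -0.99 ± 0.30, unadjusted p = 0.0150) and, with unadjusted p from 0.0551 to 0.0990, Smpdl3a (-0.31 ± 0.13), the asparagine synthetase gene Asns (-0.25 ± 0.12), Rgcc (-0.26 ± 0.13), Ghrh (-0.23 ± 0.12) and Aldoc (-0.37 ± 0.19). None of these 12 genes passed edgeR's adjustment over all genes. Vil1 is also a member of the yolk sac endoderm list given below.

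Of 20001 genes tested by edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 387 genes, 360 higher and 27 lower in the libraries labelled Slc6a4-/-, where 1000 would be expected by chance. limma-voom also called 0 and DESeq2 called 64, all higher, among them Kng2, Col9a3, Col2a1, Fmo1, Vil1 and Irf6. The groups did not overlap in 592 genes that were higher and 265 that were lower, 4.28% of the genes, where chance gives 10%. In simulated counts with the spread of these libraries, edgeR recovered 6% of the genes changed 2-fold and 81% of those changed 4-fold. The changed genes were drawn among those at a mean of 1 CPM or more, with 19602 genes tested. Where no gene had been changed, DESeq2 called 32 of 19608 genes, against 0 by edgeR and 0 by limma-voom. Simulated genes varied independently, while genes of the real libraries moved together, so these figures may not hold for the real data. Without WT replicate 1, edgeR called 1 gene, S100g, which encodes a calcium-binding protein, at a log2 fold change of 4.41 ± 0.23 (SE, adjusted p = 0.0293). With all libraries it was 2.05 (unadjusted p = 0.0875). Counts of S100g were 1923, 151 and 132 in WT replicates 1, 2 and 3 and 3151, 3609 and 3232 in the libraries labelled Slc6a4-/-; S100g was chosen after its values were seen.

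Genes of the list fixed for the yolk sac endoderm, the layer that secretes serum proteins into the yolk sac, were higher as a set in the libraries labelled Slc6a4-/-. All 33 measured members had a positive log2 fold change, with a median of 2.92 and a mean of 2.48. The alpha-fetoprotein gene Afp was at 977, 1475 and 387 CPM in the libraries labelled Slc6a4-/- replicates 1, 2 and 3 against 210, 2.82 and 30.4 in WT replicates 1, 2 and 3. The apolipoprotein gene Apob was at 147 ± 58.4 against 11.8 ± 14.97 CPM (SD, n = 3 each), and the endocytic receptor genes Cubn and Lrp2 at 60.6 ± 32.9 against 6.06 ± 6.14 and 25.2 ± 9.77 against 4.23 ± 3.76. Transthyretin (Ttr) was at 49.9 ± 23.9 against 5.44 ± 6.22 and the retinol carrier gene Rbp4 at 27.4 ± 14.6 against 3.62 ± 2.71. In 26 members every library labelled Slc6a4-/- lay above every WT library. By edgeR 23 of the 33 passed adjusted over the list alone and 0 passed over all genes.

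The list passed camera with a preset correlation (adjusted p = 2.56e-88, higher in 26 members without overlap), but its members moved with one another, with an estimated correlation of 0.68, and the adjusted p = 0.137 with an estimated correlation. The mean score of the list was -1.53 ± 1.56 in WT and 1.53 ± 0.72 in the libraries labelled Slc6a4-/- (log2, SD, n = 3 each), and its exact two-sided permutation p was 0.1, the smallest possible. WT replicate 1, at a score of 0.15, lay nearer to Slc6a4-/- replicate 3, at 0.72, than to WT replicates 2 and 3, at -2.93 and -1.83. The median was between 2.45 and 4.17 with any 1 library left out. Of the 33 members, 11 were at 1 CPM or more in every WT library, and Foxa2 is also in the list of metrial and uterine epithelium. No list was fixed for other tissues that make serum proteins, so the list cannot tell yolk sac from such tissues.

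**Figure D2:**
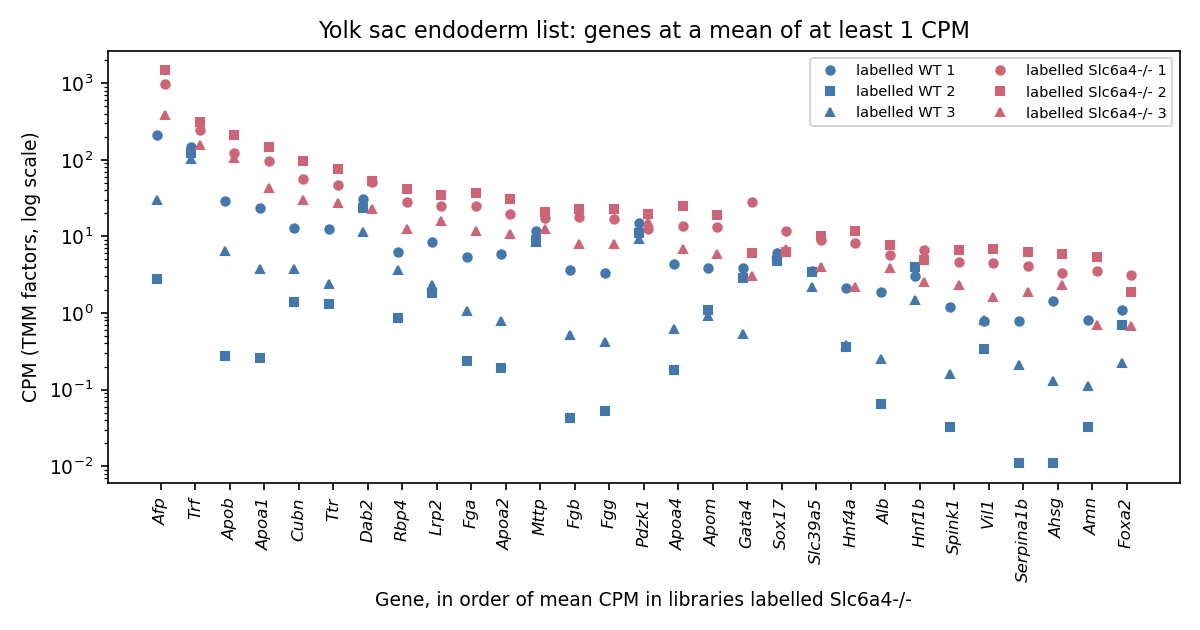
Genes of the yolk sac endoderm list with a mean of at least 1 CPM in the libraries labelled Slc6a4-/-, in CPM on a log axis, with 1 point per library. For Afp the libraries labelled Slc6a4-/- lie between 387 and 1475 CPM and those labelled WT between 2.82 and 210.

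Genes that carry sugars, lipids and monoamines formed 3 further lists called higher by camera with the preset correlation. Of the 13 measured glucose and sugar transporters, 11 were higher, with a median log2 fold change of 0.36 (adjusted p = 1.03e-08, and adjusted p = 0.137 with an estimated correlation). Slc2a2, a glucose transporter of liver and gut, was at 3.35 ± 2.03 against 0.74 ± 0.18 CPM (SD, n = 3 each) and was the 1 member that passed adjusted over the list alone (adjusted p = 0.0422, edgeR), while Slc2a3, a neuronal and trophoblast glucose transporter, was at 35.1 ± 5.97 against 24.4 ± 1.91. The serotonin and monoamine handling list had 14 of 22 members higher and a median of 0.11 (adjusted p = 0.0104, and adjusted p = 0.327 with an estimated correlation), with 0 members passing adjusted over the list alone and 4 at an unadjusted p under 0.05. Besides Slc6a4 these were Slc22a2, an organic cation transporter, at a log2 fold change of 2.24 ± 0.57 (SE), Maob, which degrades monoamines, at 2.91 ± 0.83, and Ddc, which makes serotonin from its precursor, at 0.65 ± 0.21. Lipid uptake and fatty acid transport had 17 of 29 members higher and a median of 0.01 against a mean of 0.30 (adjusted p = 0.0230, and adjusted p = 0.755 with an estimated correlation), led by Slc27a2 at 3.05 ± 0.65 and Lipc at 1.99 ± 0.58; 0 passed adjusted over the list alone and 3 were at an unadjusted p under 0.05. The monoamine call ended without WT replicate 1 (adjusted p = 0.0525), without WT replicate 3 (0.145, at a median of 0.26) and without Slc6a4-/- replicate 1 (0.357, at a median of -0.02). The lipid call ended with a filter at 1 CPM (0.498), with a term for the form of the sample names (0.0750) and without Slc6a4-/- replicate 1 (0.248, at a median of -0.02), Slc6a4-/- replicate 2 (0.167) or WT replicate 3 (0.552). With the yolk sac score as a covariate none of the 3 lists passed, with medians of 0.30 for sugars (adjusted p = 0.118), 0.21 for monoamines (0.755) and -0.09 for lipids (0.132). Every library labelled Slc6a4-/- scored above every WT library, so here and below this covariate overlaps with the genotype. A call lost or turned with it cannot be laid to either. Without the yolk sac and DESeq2-called genes, the sugar list passed (median 0.28, adjusted p = 6.09e-06) and the lipid list did not (0.170). The DESeq2-called genes were called from these same libraries and all were higher, so their removal works against both lists. The lost lipid call is therefore no separate evidence. The monoamine list holds no yolk sac or DESeq2-called gene, so the removal could not change it (0.11, 0.0104). Within their groups, Maob, Slc22a2 and Slc6a4 were highest in WT replicate 1 and lowest in Slc6a4-/- replicate 3, the order of the yolk sac score. Ddc did not have this order.

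Stromal, macrophage and cell cycle genes were also higher in the libraries labelled Slc6a4-/- by camera with the preset correlation. Mesenchyme and fibroblasts had 20 of 20 members higher and a median of 0.37 (adjusted p = 2.49e-05), smooth muscle 9 of 12 and 0.22 (0.00386), extracellular matrix remodelling 20 of 23 and 0.21 (0.00713), macrophages 12 of 18 and 0.30 (8.93e-04) and cell cycle 29 of 30 and 0.15 (6.19e-04). For each of these 5 lists the adjusted p = 0.755 with an estimated correlation, and by edgeR 0 members passed adjusted over the list alone, with 2 macrophage genes and 1 smooth muscle gene at an unadjusted p under 0.05 and 0 in the other 3 lists. The collagen gene Col3a1 was at 402 ± 133 against 272 ± 165 CPM (SD, n = 3 each), Acta2 of smooth muscle at 75.3 ± 12.1 against 54.3 ± 10.98, the mannose receptor gene Mrc1 at 10.4 ± 1.46 against 6.24 ± 2.22 and the proliferation marker Mki67 at 212 ± 30.6 against 178 ± 9.47. Each of these calls ended without 1 or more of the libraries, in some with a median close to that of all libraries. Without WT replicate 3, the adjusted p was 0.193 for mesenchyme (median 0.31), 0.461 for smooth muscle, 0.381 for matrix remodelling and 0.230 for cell cycle. Without Slc6a4-/- replicate 2 it was 0.457 for smooth muscle (median 0.23) and 0.720 for cell cycle (median 0.04). Without WT replicate 2 it was 0.105 for smooth muscle (median 0.20). Without Slc6a4-/- replicate 1 it was 0.342 for macrophages and 0.567 for matrix remodelling, whose median turned to -0.10. Slc6a4-/- replicate 1 had the highest score in macrophages (0.55, with -0.34 to 0.18 in the others) and matrix remodelling (0.81, with -0.54 to 0.07). It was also highest in decidual stroma (0.84, with -0.49 to -0.01) and immediate early genes (0.77, with -0.53 to 0.22). Erv3 of the decidual list was at 721 CPM in it and at 51.1 to 128 in the others. With the yolk sac score as a covariate, an alternative chosen after the data were seen, mesenchyme (median -0.58, adjusted p = 1.41e-04) and smooth muscle (-0.62, 0.00221) passed in the other direction. Macrophages kept their call (0.0179), and cell cycle (0.976) and matrix remodelling (0.174) did not pass.

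Spongiotrophoblast and glycogen trophoblast genes, markers of the endocrine junctional zone, were lower in the libraries labelled Slc6a4-/-, with 22 of 24 members below 0 and a median of -0.13 (camera adjusted p = 0.00179, and adjusted p = 0.755 with an estimated correlation). Ceacam12 was at 409 ± 228 against 515 ± 86.8 CPM (SD, n = 3 each) and Psg25 at 525 ± 177 against 578 ± 33.7, differences smaller than the SD of the libraries labelled Slc6a4-/-, and by edgeR 0 members were at an unadjusted p under 0.05. The call ended without WT replicate 1 (adjusted p = 0.148), without Slc6a4-/- replicate 2 (0.0528) and without Slc6a4-/- replicate 1 (0.868), where the median was 0.03. The unfolded protein and integrated stress response list had 19 of 22 members below 0 and a median of -0.11 (adjusted p = 0.00862, and adjusted p = 0.327 with an estimated correlation). In that list Asns was at 82.0 ± 6.45 against 97.5 ± 5.90, Trib3 at 6.21 ± 1.64 against 9.18 ± 2.72 and Atf4 at 167 ± 17.2 against 190 ± 8.19. Phgdh went the other way, at 55.0 ± 9.77 against 46.9 ± 5.54. By edgeR 0 members of the list were at an unadjusted p under 0.05. Its call ended without WT replicate 1 (0.135) and without Slc6a4-/- replicate 2 (0.141). The median of the stress response list was between -0.19 and -0.03 with any 1 library left out. With the yolk sac score as a covariate neither list passed (0.564 for spongiotrophoblast and 0.296 for the stress response).

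The other placental lists did not pass. Prolactin family hormones had a median of -0.12 (camera adjusted p = 0.255), placental cathepsins -0.06 (0.101), syncytiotrophoblast and labyrinth trophoblast -0.06 (0.946) and imprinted genes 0.01 (0.813). Without 1 library some did pass, again with the preset correlation of 0.01. The correlation estimated on all libraries was 0.54 for prolactins, 0.38 for cathepsins and 0.30 for syncytiotrophoblast. The p-values of these passes therefore treat members that moved together as nearly independent. Prolactins were lower without WT replicate 1 (-0.39, adjusted p = 7.92e-04) and Slc6a4-/- replicate 3 (-0.29, 3.60e-04) and higher without Slc6a4-/- replicate 2 (0.16, 0.0136), cathepsins lower without Slc6a4-/- replicate 3 (-0.47, 2.48e-05), and syncytiotrophoblast lower without WT replicate 3 (-0.30, 0.0150). Cathepsins also passed with a filter at 1 CPM (-0.14, 0.0155) and in thinned counts (-0.13, 0.0431). With the yolk sac score as a covariate, and the preset correlation, prolactins passed as higher (1.07, 2.52e-07). Prl4a1 was at 1032 ± 469 against 668 ± 278 CPM and Ctsq at 583 ± 155 against 646 ± 73.9 (SD, n = 3 each). In the syncytiotrophoblast list, Met, the receptor of hepatocyte growth factor, was at 11.8 ± 1.73 against 7.49 ± 1.48 CPM and did not pass adjusted over the list alone. In all, camera with the preset correlation called 11 of the 33 lists, 9 higher and 2 lower, with 13 at an unadjusted p under 0.05. The directions changed with single libraries, to 5 higher and 6 lower without Slc6a4-/- replicate 1, 11 and 0 without Slc6a4-/- replicate 2, 5 and 4 without WT replicate 3, 9 and 4 without WT replicate 2, and 10 and 5 without Slc6a4-/- replicate 3. With an estimated correlation camera called 0, with 4 at an unadjusted p under 0.05, and fry called 0, with 3.

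**Figure D3:**
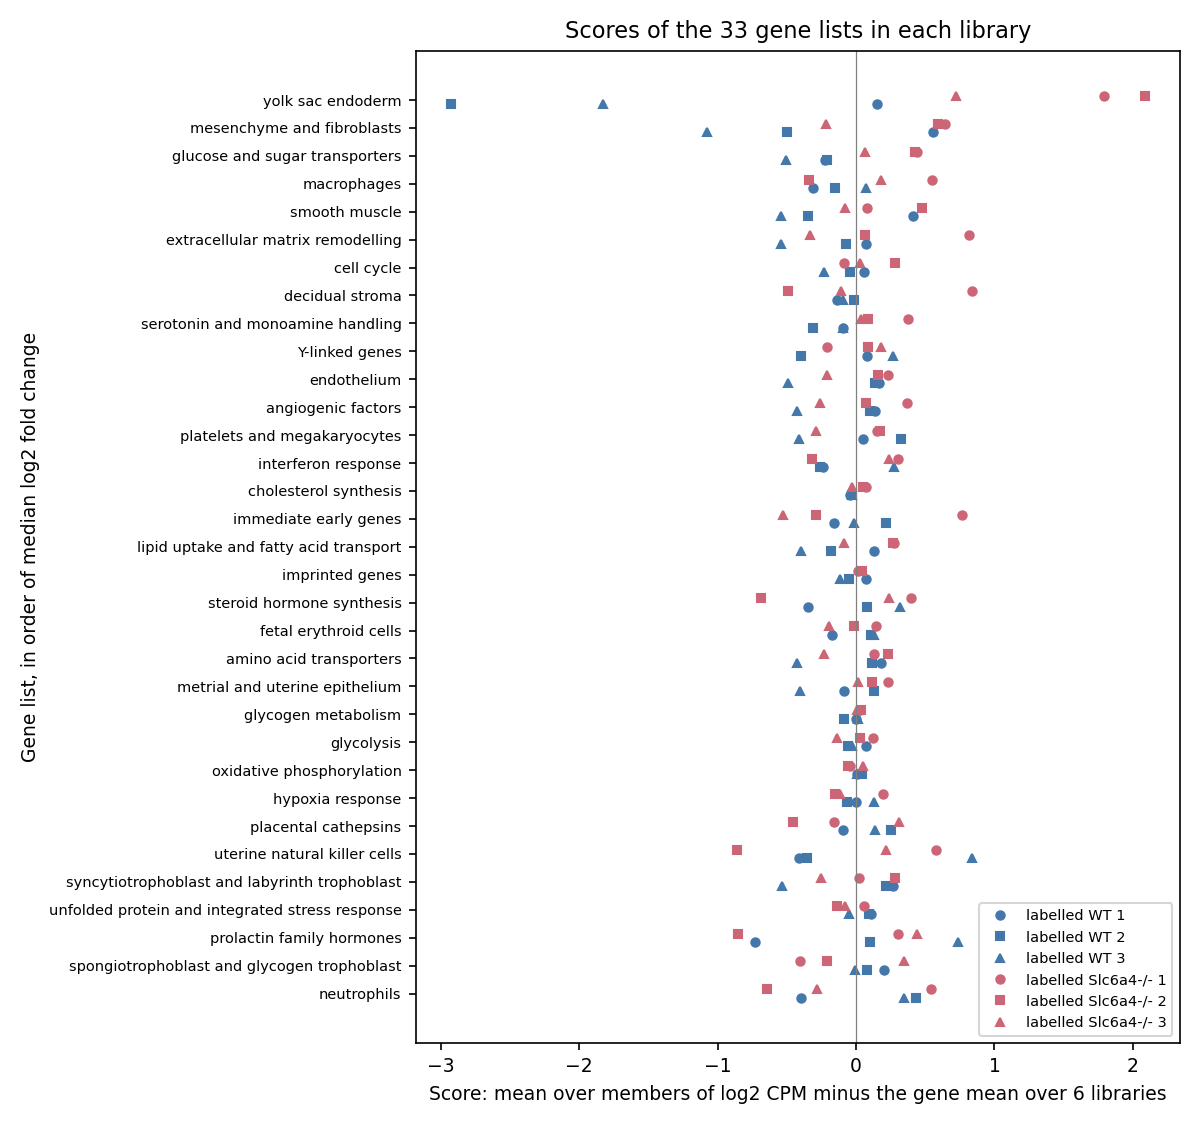
Score of each of the 33 gene lists in each library, as the mean over members of log2 CPM minus the gene's mean over the 6 libraries. In the yolk sac endoderm list the libraries labelled WT lie between -2.93 and 0.15 and those labelled Slc6a4-/- between 0.72 and 2.09.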

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

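The alternatives with the yolk sac score as a covariate, and with yolk sac and DESeq2-called genes left out of the other lists, were chosen after the data were seen. The score separates the groups, so fits with it cannot part the genotype from what raised the yolk sac genes. The DESeq2-called genes were all higher in these same libraries, so leaving them out works against lists called higher. The count of 0 changed genes by edgeR held under every alternative of the test (387 at an unadjusted p under 0.05 as reported, 82 to 782 otherwise) except DESeq2, with 64, and without 1 library, with 0 to 1 (1 without WT replicate 1). The higher Slc6a4 level kept its sign in each alternative, with a log2 fold change of 0.70 to 0.97 without 1 library and 0.34 with the yolk sac score. The count of 11 lists was 9 to 15 without 1 library, 9 with the replicate block, 7 with the yolk sac score, 10 without the yolk sac and DESeq2-called genes, and 0 with an estimated correlation and with fry. The replicate numbers do not pair the samples (correlations of deviations of -0.20, 0.15 and 0.67), and the block called 0 genes, as without it. The lipid call ended with the block (adjusted p = 0.0781), the 1 CPM filter (0.498), the term for sample names (0.0750) and without the yolk sac and DESeq2-called genes (0.170), the monoamine call with the block (0.0557) and the stress response call with no filter (0.0550). Medians in these settings were 0.0057 to 0.022 for lipids, 0.067 for monoamines and -0.10 for the stress response. As reported they were 0.014, 0.11 and -0.11. Unless said otherwise the cause of these differences was not tested. Of 1394 values of named genes, 1363 kept direction and side of the threshold, 12 passed with DESeq2 and 19 changed sign. Of 593 values of lists, 452 kept both, 51 lost a call, 20 gained one and 70 changed the direction of the test. At these depths the spread between libraries limits the results, with a chi-square per degree of freedom of at least 85.4 between replicates.

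The direction of a list is that of its test, and its value is the median log2 fold change. Fits with the yolk sac score and fits without 1 library used camera with the preset correlation. With the yolk sac score as a covariate the lists that passed were prolactin family hormones (adjusted p = 2.52e-07), mesenchyme (1.41e-04), smooth muscle (0.00221), amino acid transporters (0.0179), macrophages (0.0179), steroid hormone synthesis (0.0235) and interferon response (0.0235). Of the 10 called lists tested with it, only macrophages kept call and direction. In that alternative the direction turned for prolactin family hormones (1.07), neutrophils (0.84), steroid hormone synthesis (0.65), placental cathepsins (0.35), uterine natural killer cells (0.35), fetal erythroid cells (0.28), oxidative phosphorylation (0.12), imprinted genes (0.065), cell cycle (0.060), Y-linked genes (0.0061), glycogen metabolism (-0.020), endothelium (-0.067), lipid uptake (-0.093), extracellular matrix remodelling (-0.20), amino acid transporters (-0.22), angiogenic factors (-0.28), syncytiotrophoblast (-0.40), mesenchyme (-0.58) and smooth muscle (-0.62). Apart from left-out libraries, the other turns were in lists that did not pass as reported. They were upper-quartile factors for Y-linked genes (0.050), platelets (0.036) and syncytiotrophoblast (-0.056), RLE factors for glycogen metabolism (-0.028), the 1 CPM filter for Y-linked genes (0.071) and glycogen metabolism (-0.035), no filter for steroid synthesis (0.020), thinning for Y-linked genes (0.075), fry for steroid synthesis (0.0099) and immediate early genes (0.017), the block for glycogen metabolism (-0.013) and syncytiotrophoblast (-0.0058), and the term for sample names for glycogen metabolism (-0.012), syncytiotrophoblast (0.0086) and Xist (0.15).

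Without 1 library, medians of lists whose direction turned ranged from -0.39 to 0.37 for prolactin family hormones, -0.30 to 0.12 for syncytiotrophoblast, -0.060 to 0.058 for glycogen metabolism, -0.16 to 0.11 for amino acid transporters, -0.29 to 0.37 for decidual stroma, -0.34 to 0.51 for uterine natural killer cells, -0.026 to 0.18 for endothelium, -0.077 to 0.19 for erythroid cells, -0.20 to 0.19 for platelets, -0.067 to 0.18 for uterine epithelium, -0.083 to 0.26 for angiogenic factors, -0.085 to 0.060 for glycolysis, -0.23 to 0.26 for steroid synthesis, -0.025 to 0.11 for cholesterol synthesis, -0.021 to 0.042 for imprinted genes, -0.40 to 0.30 for immediate early genes, -0.058 to 0.21 for interferon response, -0.10 to 0.36 for matrix remodelling and -0.14 to 0.27 for Y-linked genes. Log2 fold changes of single genes whose sign turned ranged from -0.67 to 3.6e-04 for Ctsm, -0.75 to 0.025 for Ceacam14, -0.29 to 0.050 for Pcdh12, -0.42 to 0.035 for Psg25, -0.14 to 0.42 for Itga6, -0.029 to 0.33 for Vgll1, -0.37 to 0.037 for Slc16a3, -0.048 to 0.79 for Mmp9, -0.25 to 3.27 for Mmp13, -0.39 to 0.062 for Kdm5d, -0.021 to 0.32 for Ddx3y, -0.25 to 0.32 for Eif2s3y, -0.16 to 0.22 for Uty and -0.79 to 1.11 for Xist.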

Other observations

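The tests of the yolk sac genes, Slc6a4, Gm12343, the genes around Slc6a4 and the genes called by DESeq2 were chosen after the results were seen, and the counts over other splits of the libraries were planned before; the rules of 3 tests, on the ratios between yolk sac genes, on yolk sac reads in Gm12343 and on the genes around Slc6a4, were changed after their values were seen.

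Apart from genotype, the libraries numbered 3 stood apart from the others. The first principal component held 48.1% of the variance and placed WT replicate 3 at 81.1 and Slc6a4-/- replicate 3 at 39.6, with the other 4 libraries between -60.0 and -5.51. Mitochondrial genes took 3.20% and 3.57% of the counts in these 2 libraries and 2.06% to 2.24% in the others. The score of the endothelium list was -0.49 and -0.21 in WT and Slc6a4-/- replicates 3 against 0.14 to 0.23 in the others, that of platelets and megakaryocytes -0.42 and -0.29 against 0.05 to 0.32, and that of syncytiotrophoblast -0.53 and -0.26 against 0.02 to 0.28. Of the lists called, extracellular matrix remodelling scored -0.54 and -0.34 in these 2 libraries against -0.07 to 0.81 in the others, and mesenchyme -1.08 and -0.22 against 0.55 to 0.65 in 3 of the others and -0.50 in WT replicate 2. Prolactin family hormones scored 0.74 and 0.44 in WT and Slc6a4-/- replicates 3 against -0.85 to 0.30 in the others. Their short sample names also set these 2 libraries apart in the labels.

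Transcripts of the Y chromosome were present in each of the 6 libraries. Ddx3y was at 78.7, 75.9 and 113 CPM in WT replicates 1, 2 and 3 and at 84.0, 89.2 and 120 in the libraries labelled Slc6a4-/-. Eif2s3y was lowest in WT replicate 2, at 15.6 CPM against 28.5 to 44.8 in the other 5 libraries, and Kdm5d in Slc6a4-/- replicate 1, at 12.9 against 23.7 to 27.2. Xist, transcribed from an inactive X chromosome, ranged from 7.02 CPM in Slc6a4-/- replicate 2 to 74.4 in WT replicate 3.

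The remaining lists did not pass camera with the preset correlation on all libraries. Medians of log2 fold change were -0.30 for neutrophils (adjusted p = 0.0939), -0.04 for hypoxia response (0.151), -0.03 for oxidative phosphorylation (0.151), 0.07 for endothelium (0.223), 0.02 for interferon response (0.231), 0.06 for angiogenic factors (0.287), 0.11 for decidual stroma (0.405), -0.01 for metrial and uterine epithelium (0.411), 0.0044 for fetal erythroid cells (0.569), -0.03 for glycolysis (0.657) and -0.06 for uterine natural killer cells (0.657). They were 0.02 for immediate early genes (0.813), 0.02 for cholesterol synthesis (0.813), -0.0041 for amino acid transporters (0.883), 0.03 for platelets and megakaryocytes (0.946), 0.0099 for steroid hormone synthesis (0.946), -0.01 for glycogen metabolism (0.946) and 0.08 for Y-linked genes (0.986). Several passed without 1 library, again with the preset correlation of 0.01. For the lists that did, the correlation estimated on all libraries was between 0.14 (endothelium) and 0.77 (uterine natural killer cells). These passes therefore treat members that moved together as nearly independent. Uterine natural killer cells were lower without Slc6a4-/- replicate 1 (-0.28) and WT replicate 2 (-0.34) and higher without Slc6a4-/- replicate 2 (0.26) and WT replicate 3 (0.51), and decidual stroma was lower without Slc6a4-/- replicate 1 (-0.29) and higher without Slc6a4-/- replicate 2 (0.37). Without Slc6a4-/- replicate 1, neutrophils (-0.41), hypoxia response (-0.15) and immediate early genes (-0.40) were lower. Without WT replicate 1, neutrophils were lower (-0.62). Without WT replicate 2, hypoxia response was lower (-0.10) and endothelium higher (0.14). Without Slc6a4-/- replicate 2, interferon response (0.20) and steroid hormone synthesis (0.25) were higher. Without WT replicate 3, interferon response was higher (0.21) and amino acid transporters lower (-0.16). Without Slc6a4-/- replicate 3, angiogenic factors were higher (0.26) and oxidative phosphorylation lower (-0.06), the latter also with the term for sample names (-0.03). The median and the direction of the test differed in sign for metrial and uterine epithelium, fetal erythroid cells, immediate early genes, amino acid transporters, steroid hormone synthesis, glycogen metabolism and syncytiotrophoblast.

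The yolk sac genes may come from differing amounts of yolk sac tissue in the dissected pieces, since within WT alone the score ranged from -2.93 to 0.15. Over the 30 of 33 members higher both in WT replicate 1 than 2 and in Slc6a4-/- replicate 2 than 3, the log2 ratio of these increments had an SD of 0.88. It was 0.98 over 234 other genes higher in both pairs. The other genes had to pass a minimum fold and a minimum level, which the members did not, and were not cleared of DESeq2-called genes. The SDs are therefore not alike and do not separate a single source from shared control (an SD under 1 was first to count for a single source). Over the 10 most abundant members the SD was 0.33, against 0.84 over the 10 most abundant of the other genes. These genes were ranked by their level in Slc6a4-/- replicate 2, which is also in the ratio. Shared control of the members could give a small SD as well, so this does not separate it from a single source either. The amount of tissue cannot be told apart from an effect of the genotype, with a gap of 0.57 (log2) between the lowest score of a library labelled Slc6a4-/- and the highest of WT. The median of the list was 2.92 in thinned counts. CPM already divide by the library total, so thinning could hardly move this median and does not test a difference in library size. A lower share of trophoblast is argued against by the other cell types, whose highest median was 0.37. Of the 58 genes that DESeq2 called outside the list, 81.0% had WT replicate 1 highest and Slc6a4-/- replicate 3 lowest of their groups, against 84.8% of the list and 18.9% of the other genes, so they may share what raised the list, whichever that is.

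The higher level of Slc6a4 in the libraries labelled Slc6a4-/- may also go with the yolk sac genes. The summed CPM of the yolk sac list was higher in every library labelled Slc6a4-/- than in every WT library, so it overlaps with the genotype. With this sum as a term of a linear model of the 6 libraries, the difference between the groups was 1.65 ± 0.98 CPM (SE), against 5.32 without the term. An exchange of the group labels cannot be told apart from this, because the part of the gene that was deleted is not given in the sources used here and Gm12343 had a summed count of 2 in the libraries labelled WT. An effect of the targeted allele on the level of the remaining exons was not tested.

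For Gm12343, the lower 95% bound of its ratio, 5.96, was above the ratio of 1.79 of Slc6a4. Taken alone, this goes against unspliced Slc6a4 RNA in proportion to Slc6a4 itself. The bound covers counting error only, and the gene was chosen for its separation of the groups. Unspliced RNA is therefore not excluded. Both ratios were taken from library totals without TMM factors. Slc6a4-/- replicate 3 had 911 CPM of summed yolk sac genes, against 1882 and 2735 in replicates 1 and 2. Its count of 18 was not below their counts of 15 and 17, which goes against reads from yolk sac tissue. WT replicate 1, at 564 CPM of these genes, had 1 count with an upper 95% bound of 5.57. The lower bound of Slc6a4-/- replicate 3 was 10.7, which also goes against reads in proportion to these genes. Both comparisons rest on Slc6a4-/- replicate 3, and Gm12343 was chosen for its low counts in WT. Reads from yolk sac tissue therefore stay open as a source (they were first to count as excluded). An effect of the targeted allele stays open without support of its own, since the gene was chosen for the separation of the groups, with at least 15 counts against at most 1. Which allele gives the reads could also be the other way round if the labels were exchanged.

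DNA of another strain around the targeted gene was looked for as a hypothesis. Within 10 Mb of Slc6a4 the groups did not overlap in 17 of 376 genes, 4.52%, against 4.28% elsewhere, an odds ratio of 1.06 with an upper 95% bound of 1.73. Within 5 Mb they did not overlap in 12 of 165 genes, 7.27%, against 4.26% elsewhere, an odds ratio of 1.76 (Fisher's exact test, p = 0.0772). Among these genes are Slc6a4 and Gm12343, already known to separate the groups, and Aldoc. The bound was 3.19 within 5 Mb and 1.602 within 20 Mb, so the narrow window leaves the hypothesis open. The test was first set on 10 Mb alone, where a bound under 2 would have argued against the hypothesis, and was widened to the 3 windows after their values were seen.

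The 6 libraries can be split in 10 ways, too few for a share under 0.05. By edgeR 0 genes were called in the real split and the highest of the other splits was also 0, so all 10 splits gave as many. Of the gene lists 11 were called in the real split and 15 in the highest of the others, and 6 of the 10 splits gave as many. The split of WT replicates 1 and 2 and Slc6a4-/- replicate 2 against the rest had 4245 genes at an unadjusted p under 0.05 against 387 in the real split, and DESeq2 called 1312 genes in it against 64, which points to a structure of the samples other than genotype.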
